A study of Mus musculus with 2 samples.

How the data were processed

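The superior cervical ganglion is the uppermost ganglion of the sympathetic chain, and its neurons innervate targets in the head and neck. Left and right ganglia of 4 C57BL/6 mice aged 15 weeks, 2 females (mice 1 and 2) and 2 males (mice 7 and 8), were taken for single-nucleus RNA sequencing. Per the labels, the nuclei of each ganglion were marked with a hashtag, an antibody that carries a DNA barcode, and all 8 ganglia were pooled in a single droplet library made with 10x Genomics 3' v3 chemistry. The library was sequenced as 150 bp paired-end reads. The deposited hashtag list names the mouse, sex and side behind each hashtag, and ganglia were grouped from it.

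The deposited matrix holds raw UMI (unique molecular identifier) counts for 32285 genes and 8 hashtags, made by the authors with Cell Ranger 7.0.0 and build mm10 per the submitters' processing notes. The barcodes had been selected before deposit: no barcode held fewer than 500 gene UMI counts. Whether intronic reads or strand entered the counting is not given in the sources used here. Nuclei hold much unspliced RNA, so a gene's span can enter its count. Genes that overlap or share near-identical sequence are given as uncertain: Tsix with Xist, Hspa1a with Hspa1b, H2-D1 with other class I genes, Gm17268 with Ccl2, Chat with Slc18a3, and Gm47283, which is annotated on the Y chromosome. Positions are those of GENCODE M21 on GRCm38, the assembly behind mm10, in which 32235 of the 32285 gene IDs were found. They are whole gene spans, because 3' counts per gene are not assigned to an exon, intron or UTR.

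Barcodes with at least 500 genes and at most 5% mitochondrial counts were kept. Hashtags were called with HTODemux (Seurat 5.3.0, centred log-ratio values, positive quantile 0.99), which compares each hashtag with its own background. Scrublet (scanpy 1.11.5, expected rate 0.08) marked 0 nuclei as doublets and has not worked here, so doublets were removed only as nuclei with 2 or more hashtags. An alternative that removed the 8% of nuclei with the highest Scrublet scores was added after seeing the data. Doublets of nuclei from the same ganglion remain.

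Nuclei with a single hashtag were scaled to 10000 counts and clustered with the Leiden method (leidenalg 0.10.2, resolution 0.5) on 2000 variable genes, 30 components and 15 neighbours. Xist, Tsix, Y-linked and mitochondrial genes were left out of the clustering. Clusters were called X-like from marker lists fixed before the data were examined, by the list with the highest mean log2 fold over the other clusters among those with at least 3 markers at a log2 fold of 1 or more (prior of 5 CPM). A cluster with mitochondrial or satellite-repeat genes among its top 10 (of genes seen in at least 10% of its nuclei) stayed unnamed. These naming thresholds were set after seeing the data. They left cluster 7 unnamed, which held 2.91% ± 0.123 (SD, n = 2 mice) of the nuclei of the females and 3.18% ± 0.822 (n = 2) of those of the males. The glia-like class joins clusters 1, 2, 3, 4 and 6. Cxcl10, a chemokine gene, Dnajb1, a co-chaperone gene, and Ccn1 are among the 10 leading genes of cluster 1. Pooled over the mice of a sex, cluster 1 held more of the glia of the females than any other cluster and cluster 3 more of those of the males, although in mouse 2, a female, cluster 3 held more than cluster 1. Both were also tested on their own, and clusters 2, 4 and 6 were not. Levels in CPM, UMI counts as parts of the class total, were taken from summed UMI counts of a class. Shares of nuclei with a UMI were also computed after thinning each nucleus to 1000 UMI counts, which left out 83 glia, 3 endothelial, 2 fibroblast, 6 mural, 1 perineurial, 8 myelinating Schwann, 4 macrophage and 48 unnamed nuclei and 0 neurons.

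Cells are not replicates, so UMI counts were summed per ganglion or per mouse within a class, where a sum held at least 20 nuclei, and tested with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3, TMM scaling, filterByExpr) with Benjamini-Hochberg adjustment at a false discovery rate of 0.05. The fit of fibroblasts in left ganglia alone was run below this limit, with 12 nuclei in mouse 7. Sides were compared over 8 ganglia with the mouse as a block, sexes over 4 mice with both sides summed, and a sex by side term over 8 ganglia with the mouse as a block. The block comes from the mouse numbers in the hashtag list, since both ganglia of a pair came from the same mouse. After removing group means, the correlation of the left and right ganglia across neuron genes was -0.184 in females and 0.314 in males, and across glia genes -0.0994 and 0.109. In endothelial nuclei it was 0.101 and 0.0514, in glia cluster 1 0.0284 and 0.0214, and in glia cluster 3 -0.188 and 0.186. DESeq2 1.42.0 was the other tool. Other alternatives were other hashtag callers, looser and stricter filters on nuclei, other resolutions and scalings, no filter on low counts and each mouse left out in turn. Shares of classes were compared with exact sign-flip or permutation tests, two-sided.

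Fixed gene lists, 21 in all with 226 genes, were tested with camera (limma 3.58.1, preset correlation 0.01), with camera under an estimated correlation, and with fry, where at least 3 members were measured. The genes named are the sex-linked lists, the 10 called genes with the largest rise and the 10 with the largest fall that changed the same way in every mouse, called members of the fixed lists, or, with no call, the 5 with the smallest p. Some listed genes are not reported here. These lists, the gene rule, the designs and most alternatives were chosen before the data were examined. Later additions were the top Scrublet scores, glia clusters 1 and 3, balanced cell mixes, classes from all nuclei, the neuron sub-clusters, the alternative fits of the sex by side term and a crossed pairing of the females.

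The fits were tested on simulated data drawn from the real means and library sizes, with 200 changed genes. Each gene was drawn on its own with the spread fitted for its level, without mouse effects or differences in cell mix. Recovery in the real data can therefore be lower than the shares below. Of genes changed 2-fold between sides, 78% were recovered in neurons, 80% in glia and 51% in endothelial nuclei. Between the sexes the 2-fold shares were 50% in neurons, 70% in glia, 42% in endothelial nuclei and 16% in fibroblasts, and the 4-fold shares were 84%, 93%, 87% and 81%. A lowess offset over gene span was tested likewise in neurons: with a span trend added to the simulated counts, it left 14 calls from the trend in place of 2602, and recovered 89.5% of genes changed 4-fold. Intervals of 95% confidence (exact binomial for shares, exact Poisson for counts) and floors of 3 counts cover counting error only.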

Results

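Left and right superior cervical ganglia of 4 mice were profiled in a single pooled library of nuclei, with 1 hashtag for each of the 8 ganglia. The gene matrix held 73611163 UMI counts over 10719 barcodes, with a median of 3352 UMI counts and 1821 genes per barcode. The hashtag counts came to 4675917, with a median of 229 per barcode. The filter on genes and mitochondrial counts kept 10337 barcodes (96.4%). Of these, 5900 nuclei carried a single hashtag (57.1%, exact binomial 95% interval 56.1 to 58.0), 1218 carried more than 1 and 3219 carried none above background. Nuclei with a single hashtag had a median of 3710 gene UMI counts, those with several hashtags 5368 and those with none 2516. A ganglion contributed 585 to 976 nuclei and 3995371 to 8112692 gene UMI counts, and its median per nucleus lay between 3190 and 4554.

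The series set out to multiplex nuclei of small ganglia, so transcripts of the sex chromosomes, which no hashtag sets, were read against the sex named for each hashtag. These transcripts can show a swap between a male and a female. They cannot check left against right or the mice of a sex against each other. Xist, the RNA that coats the inactive X chromosome (ENSMUSG00000086503, GRCm38 chromosome X, 103460366 to 103483254), stood at 510 CPM in nuclei with a hashtag of a female and 21.0 CPM in those of a male, 4.11% of the level in females. The summed Y-linked genes Ddx3y, Uty, Eif2s3y and Kdm5d stood at 229 CPM in nuclei of males and 6.91 CPM in those of females, 3.02% of the level in males. Xist was detected in 72.7% to 79.9% of nuclei under the 4 hashtags of females and in 6.21% to 7.22% under the 4 of males, who should lack it. Y-linked transcripts were found in 52.8% to 55.5% of nuclei of males and 2.82% to 3.93% of those of females. Xist and a Y-linked transcript occurred together in 2.54% of nuclei with a single hashtag (exact binomial 95% interval 2.16 to 2.98), in 12% of those with several and in 1.52% of those with none. The called hashtag was also the one with the highest raw count in 57.5% of nuclei, since each hashtag was read against its own background.

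**Figure D1:**
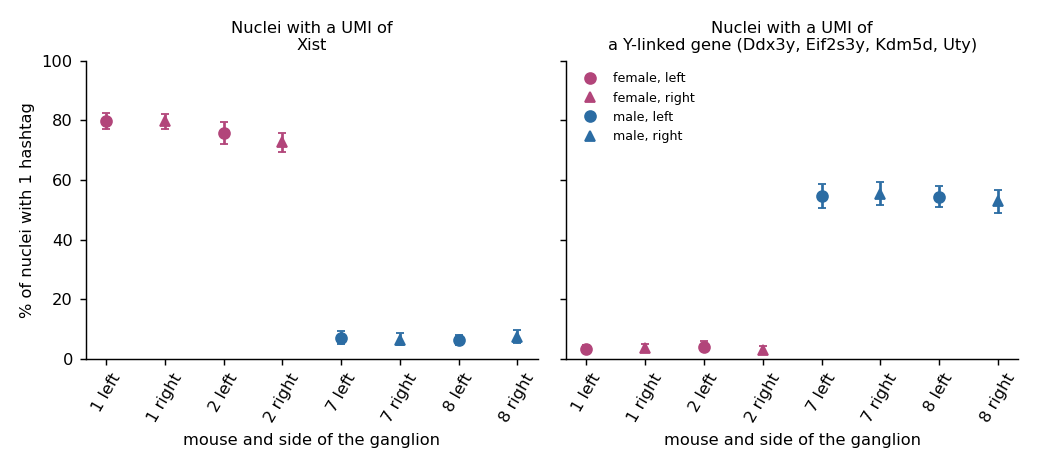
Share of nuclei (%) with a Xist UMI and with a UMI of the 4 Y-linked genes under each of the 8 hashtags, with exact binomial 95% intervals; circles are left and triangles right ganglia. Hashtags of females lay between 72.7% and 79.9% for Xist, and hashtags of males between 6.21% and 7.22%.

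Glia-like nuclei were the most numerous of the nuclei with a single hashtag, and neuron-like nuclei the deepest. Glia-like nuclei were 71.6% of the 5900 (SD 3.57 over 8 ganglia) and neuron-like nuclei 10.1% (SD 2.51), while neurons held 51.2% of the UMI counts of these nuclei and glia 36.4%. The neuron class includes sub-clusters of 85 nuclei led by glial genes and of 98 nuclei in which sensory neuron markers were higher on average. In the whole neuron class 23 nuclei held a UMI of at least 3 of the 6 sensory markers. Endothelial-like nuclei were 6.34% (SD 2.69) and fibroblast-like nuclei 4.63% (SD 1.44). Mural-like nuclei were 1.22%, perineurial-like 1.08%, myelinating Schwann-like 1% and macrophage-like 0.949%, and 3.05% were left unnamed. Leading genes of the clusters were Fgf14 and Rbfox1 in neurons, Flt1 and Pecam1 in endothelial nuclei, Lum and Pdgfra in fibroblasts, Myh11 in mural, Cldn1 in perineurial, Prx in myelinating Schwann and Mrc1 in macrophage nuclei. Glia clusters 1, 2, 3, 4 and 6 were led by Cxcl10, Apoe, Cdh19, Flnc and Nuak2 among others. The median depth was 30935 UMI counts in neurons, 3442 in glia, 6643.5 in endothelial nuclei and 3292 in fibroblasts. Th was found in every class. It stood at 542 CPM in neurons and at 89.3 CPM in glia, which should lack it. Free RNA in droplets and doublets of nuclei from the same ganglion are possible sources. Th was found in 26.5% of glia and Slc6a2 in 63.5%, at a median depth far below that of neurons. Nuclei with several hashtags were fewer, at 11.8% of the kept nuclei. These values argue against doublets within a ganglion as the main source in glia and leave free RNA open. The part of each was not measured.

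**Figure D2:**
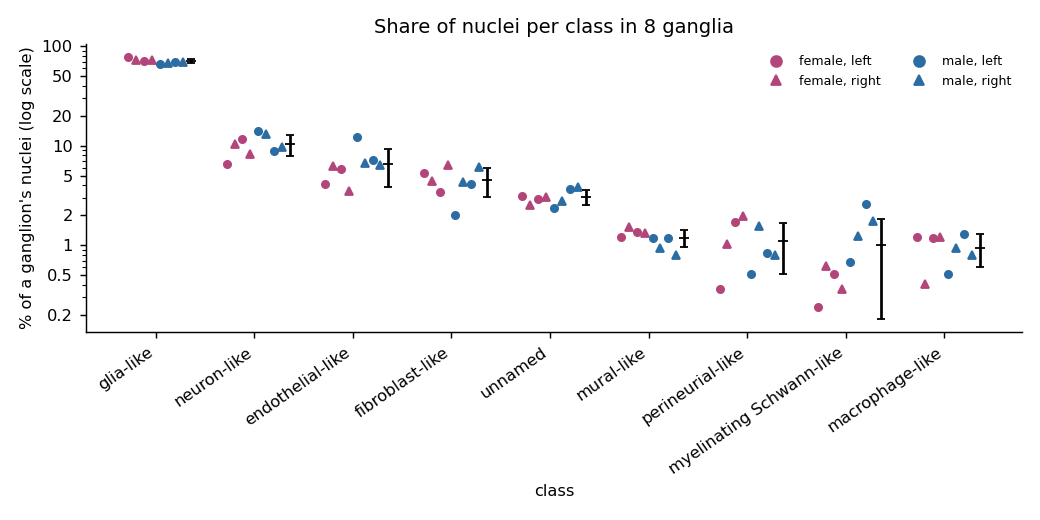
Share of nuclei (%, log axis) of each class in each of the 8 ganglia; colours mark the sexes, shapes the sides, and black bars the mean ± SD over the 8 ganglia. Glia held 71.6% and neurons 10.1% of all nuclei.

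The neurons carried the noradrenergic set. Slc6a2, the noradrenaline transporter, stood at 3076 CPM (exact Poisson 95% interval 3053 to 3099, SD 153 over 8 ganglia) in neurons against 303 CPM in glia. It was detected in 99.8% of neurons (86.2% after thinning) and 63.5% of glia (27.8% after thinning). Dbh, which makes noradrenaline from dopamine, stood at 1203 CPM (SD 120) against 196, the vesicular transporter Slc18a2 at 1062 against 102, and Cyb561 at 969 against 121. The neuropeptide Npy reached 1125 CPM with 784 to 1741 CPM in single ganglia, Gal 616 CPM and Scg2 338 CPM. Of the receptors for acetylcholine, Chrm2 stood at 463 CPM (15.2 in glia) and the nicotinic subunit Chrna3 at 359 (36.7). The neurotrophin receptor gene Ngfr stood at 757 CPM, and the regeneration-associated gene Gap43 at 783. Potassium channel genes included Kcnq5 at 1521 CPM (238 in glia), Kcnq3 at 1295 (31.6) and Kcnd2 at 556 (8.01), sodium channels Scn9a at 388 (59.3), and calcium channel subunits Cacna2d3 at 505 (10.2) and Cacna1b at 399. Of 226 listed genes, 85 were at least 2 times higher in neurons than in glia.

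Some listed genes lay near or below the floor of neurons, 0.132 CPM for 3 counts. The cholinergic genes Chat and Slc18a3, which overlap, had 5 and 8 counts (0.221 and 0.353 CPM), while Ache stood at 223 CPM. Slc5a7 stood at 11.4 CPM with an SD of 14.2 over 8 ganglia, from 1.23 to 43.4 CPM in single ganglia, and at 8.72 CPM without the left ganglion of mouse 1, the highest. Pnmt, the enzyme that makes adrenaline, had 1 count, Penk 2 and Tac1 2. Pdyn, Nts, Cck, Chrm5 and Sprr1a had 0 counts, which allows up to 0.132 CPM at this depth. The steroid hormone receptors Nr3c1 and Esr1 stood at 42.1 and 14.1 CPM.

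Glia carried myelin and stress-response transcripts, neither of them particular to glia. Mbp stood at 307 CPM, against 4201 in myelinating Schwann and 248 in macrophage nuclei. The heat-shock gene Hspa1a stood at 5314 CPM (177 in neurons), Jun at 4399 and Fos at 4162. The mean log2 CPM of the immediate early list in females was 10.4 in glia, 9.48 in endothelial nuclei, 9.74 in fibroblasts and 5.87 in neurons. In males it was 9.74, 9.41, 9.51 and 5.51. Of the cholesterol synthesis list, Hmgcs1 stood at 1167 CPM (885 in neurons). The channel genes Scn7a (600 CPM, 40.5 in neurons), Kcna2 (398, 21.9) and Kcna1 (325, 12.7) were higher in glia. The class I antigen-presenting gene H2-D1 stood at 1287 CPM in endothelial nuclei (370 in neurons). The matrix gene Dcn stood at 8380 CPM in fibroblasts and the class II gene Cd74 at 1713 in macrophages. Of the nuclear RNA list, Malat1 stood at 24581 CPM in neurons and 69291 in glia. These levels were not tested between classes, which were made from the same counts.

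The first comparison asked whether left and right ganglia differ. No class share passed its test, and no gene passed in neurons, glia or endothelial nuclei. A few fixed lists passed camera with the preset correlation alone, such as calcium channels in neurons and collagens in endothelial nuclei. Neurons were 10.4% ± 2.01 (SD, n = 4) on the right and 10.3% ± 3.26 on the left. Glia were 71.1% ± 2.46 and 71.4% ± 4.86, endothelial nuclei 5.73% ± 1.46 and 7.37% ± 3.59, and fibroblasts 5.34% ± 1.11 and 3.73% ± 1.37, higher on the right in 3 of 4 mice. The exact sign-flip p was 1 for neurons, 0.875 for glia, 0.375 for endothelial nuclei and 0.25 for fibroblasts, and could not go below 0.125 with 4 mice.

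In neurons, 0 of 12518 genes passed the edgeR test (190 at an unadjusted p under 0.05, 0 with DESeq2). The 190 were 1.52% of the genes, and the counts given next for glia and endothelial nuclei were 2.38% and 3.64%. No difference would give a share of about 0.05, so these fits may be conservative. The 5 genes with the smallest p, none of them called, were Adcyap1, which encodes the neuropeptide PACAP, Ttn, Flrt2, Cidea and the potassium channel Kcnc2. Adcyap1 stood at 12.6 CPM ± 12.9 on the right and 3.07 ± 2.37 on the left (SD, n = 4), a log2 difference of 1.93 (SE 0.31, edgeR adjusted p = 1), higher on the right in 4 of 4 mice. Flrt2 is among the leading genes of neuron sub-cluster 4, in which sensory neuron markers were higher on average, and Cidea is among the leading genes of sub-cluster 5. In glia, 0 of 11802 genes passed (281 at an unadjusted p under 0.05, 0 with DESeq2). The smallest p was that of the collagen gene Col19a1, at 8.24 CPM ± 1.40 on the right and 19.7 ± 4.33 on the left, followed by Pappa, Gm11146, Flrt2 and Dmac2l. In endothelial nuclei, 0 of 5849 genes passed (213 at an unadjusted p under 0.05, 0 with DESeq2), and Gm609, Igfbp6, Dcn, Tubb2b and Ccn2 came first. Igfbp6 leads the perineurial cluster and Dcn is a fibroblast marker. With glia cluster 1 alone 0 genes passed in edgeR and DESeq2 (404 at an unadjusted p under 0.05), with 1 called without mouse 8. With cluster 3 alone 0 passed (261), with 5 called without mouse 2. With no filter on low counts 38 genes passed in neurons, 7 in glia, 12 in endothelial nuclei, 13 in glia cluster 1 and 12 in glia cluster 3.

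Of the fixed lists, voltage-gated calcium channels were higher on the right in neurons (camera adjusted p = 0.00333, adjusted p = 0.700 with an estimated correlation) and interferon and class I genes lower (adjusted p = 0.0180, and 0.700 with an estimated correlation). Across neuron genes the right-against-left change rose with gene span (Spearman correlation 0.185, and 0.00449 with the span trend taken out). Whether these lists follow that trend was not tested. In endothelial nuclei, collagens and matrix (adjusted p = 0.000176, and 0.590 with an estimated correlation), immediate early genes (0.000219, and 0.590) and cholesterol synthesis (0.0128, and 0.743) were higher on the right. In glia 0 of 18 lists passed camera and the smallest adjusted p was 0.0933. Within glia clusters 1 and 3 alone, 2 of 16 lists passed camera in each (smallest adjusted p = 7.14e-05 and 5.17e-05). With an estimated correlation the smallest were 0.817 and 0.820. No member of these lists was called on its own among all genes, and 0 lists passed fry or camera with an estimated correlation. Without mouse 2, 0 lists passed in neurons and 1 in endothelial nuclei, and without mouse 1, 9 passed in neurons.

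The second comparison set the 2 males against the 2 females. In every class tested, sex-chromosome genes led. In glia many autosomal genes changed as well: immediate early and heat-shock genes were lower in males, and several circadian clock genes were higher. Channel genes of glia changed in both directions, with Hcn2 and Kcnj10 higher and Kcna1 lower in males. At resolution 0.3 Kcnj10, and at 1.0 Kcna1, are also among the leading genes of glia clusters. A different cluster mix therefore stays open as part of these changes. Neurons showed only sex-linked calls in edgeR, and endothelial nuclei and fibroblasts a few more.

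In glia, 544 of 13495 genes passed the edgeR test, 140 higher and 404 lower in males, of which 20 lie on the X and 6 on the Y chromosome. Xist fell by 4.46 on the log2 scale (28.7 CPM ± 0.812 in males, 609 ± 66.6 in females, SD, n = 2, BH adjusted p = 2.45e-12). All 4 Y-linked genes rose, with Ddx3y (ENSMUSG00000069045, chromosome Y, 1260771 to 1286629), an RNA helicase, at 93.6 CPM ± 5.32 against 4.63 ± 0.330. Each called gene named between the sexes stood on its side in both males against both females. For the largest rises and falls the rule that picked them required this, so it adds no support to them. Of 6 X-linked genes of silencing and escape from it, 5 fell and all 6 adjusted over the list alone. On the log2 scale Ddx3x fell by 0.96, Kdm6a fell by 0.88 and Kdm5c fell by 0.73, and Eif2s3x lay at -0.51 with an edgeR adjusted p = 0.0724. Outside the sex-linked lists 535 genes passed, 136 higher and 399 lower. The largest rises there were those of Gm34544, Gm42884, Mecom, Zfp663, 9630014M24Rik and Adam12, a metalloprotease gene (1.52 on the log2 scale, 46.3 CPM ± 12.2 against 16.1 ± 10.2, edgeR adjusted p = 0.00464, higher in 2 of 2 males). Mecom is also among the leading genes of the endothelial cluster. The largest falls were those of Kctd8, 2010013B24Rik, Slc16a12, Gm32389, Gm3294, Fer1l5, the interferon-induced GTPase gene Tgtp2 and Gm3336. Kctd8 (chromosome 5, 69109285 to 69341679) fell by 3.05 on the log2 scale, from 7.27 CPM ± 2.89 in females to 0.861 ± 0.822 in males. Without mouse 1 the count was 118 and without mouse 7 it was 914, and in these fits the lone mouse of a sex is assumed to vary like the other sex. Left ganglia alone gave 443 calls, of which 357 were among the 544, and right ganglia alone 11. MULTIseqDemux hashtag calls gave 110, the margin rule of hashtag calls 29 and DESeq2 331. MULTIseqDemux left 27 nuclei in the left ganglion of mouse 8, against 838 with HTODemux. The margin rule gave 2289 of its 3336 nuclei to the right ganglion of mouse 1. The counts from these callers are therefore not checks at like numbers of nuclei per ganglion.

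Of 20 measured immediate early and dissociation genes, 13 fell in males, 0 rose and 7 did not pass; adjusted over the list alone all 20 fell. The co-chaperone gene Dnajb1 (chromosome 8, 83608193 to 83612653) fell by 0.92 on the log2 scale (753 CPM ± 16.5 against 1375 ± 83.3, edgeR adjusted p = 0.000884) and the stress-induced factor Atf3 (chromosome 1, 191170296 to 191218039) by 0.89 (758 ± 10.9 against 1355 ± 72.7, adjusted p = 0.0011). Hspa1a, Klf4, Fosb and Egr1 fell by 0.79, 0.75, 0.72 and 0.70. The list as a whole was lower in males (camera adjusted p = 5.69e-29, adjusted p = 0.262 with an estimated correlation). The median log2 change of the list was -0.61 in glia, -0.26 within glia cluster 1 alone and -0.54 within cluster 3 alone. Within cluster 1, 3 of the 20 fell (10 adjusted over the list alone), and within cluster 3, 2 of 20 (13 adjusted over the list alone). Of 6 injury and regeneration genes 3 fell, also adjusted over the list alone (Atf3, Gadd45a and Gap43, camera adjusted p = 1.19e-05, and 0.256 with an estimated correlation), with a median log2 change of -0.60. Within cluster 1 alone, 0 of the 5 measured passed edgeR (1 lower adjusted over the list alone), with a median of -0.02 and a camera adjusted p = 0.554. Within cluster 3 alone, 1 of 5 fell (2 adjusted over the list alone), with a median of -0.32. Of 11 interferon and class I genes 3 fell, also adjusted over the list alone (Stat2, Ifit1 and Irf9, adjusted p = 0.00417, and 0.571 with an estimated correlation), with a median log2 change of -0.32. Within clusters 1 and 3 alone, 0 of 11 and 0 of 10 passed edgeR (1 lower in each adjusted over the list alone). The medians there were -0.05 and -0.09, with camera adjusted p = 0.396 and 0.335. Dnajb1 is also among the leading genes of glia cluster 1. Pooled over mice, cluster 1 held more of the glia of females than any other cluster and cluster 3 more of those of males, but in mouse 2, a female, cluster 3 held more than cluster 1. Cluster 4, led by Flnc among others, held 18.6% of the pooled glia of females and 9.62% of those of males. In single ganglia it held 13.5% to 21.4% in females and 6.15% to 16.6% in males, and it was not tested on its own.

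**Figure D3:**
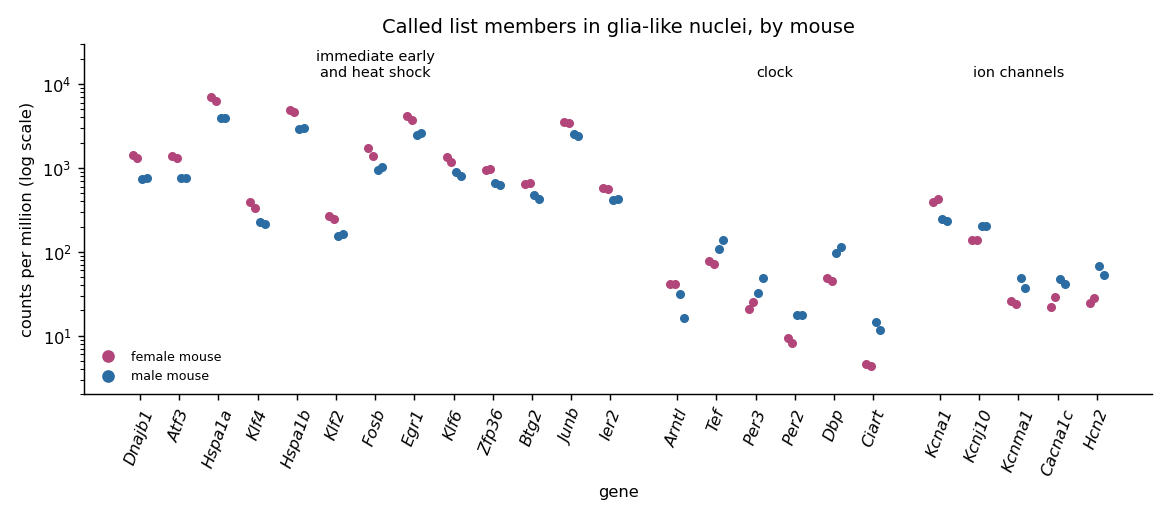
Level (CPM, log axis) in glia-like nuclei of called members of the immediate early, clock and channel lists in each of the 4 mice. For Dnajb1 the males stood at 753 ± 16.5 and the females at 1375 ± 83.3 (SD, n = 2).

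Of 12 clock genes 5 rose, 1 fell and 6 did not pass, likewise adjusted over the list alone. The clock output gene Dbp (chromosome 7, 45705088 to 45710203) rose by 1.13 on the log2 scale (106 CPM ± 13.5 against 46.8 ± 3.21, edgeR adjusted p = 0.000251), with Ciart at 1.47, Per2 at 0.93, Per3 at 0.77 and Tef at 0.67. Arntl, the partner of Clock in the positive limb, fell by 0.87 (23.7 ± 10.7 against 41.2 ± 0.146, adjusted p = 0.0301). The list was higher in males (camera adjusted p = 0.00157, adjusted p = 0.262 with an estimated correlation). Within glia cluster 1 alone 2 clock genes rose and 0 fell (5 and 2 adjusted over the list alone, camera adjusted p = 0.00265, and 0.411 with an estimated correlation). Within cluster 3 alone 1 rose and 1 fell (4 and 2 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.104). Of 16 potassium and HCN channel genes 3 rose and 1 fell (3 and 3 adjusted over the list alone): the pacemaker channel gene Hcn2 rose by 1.15 (60.6 CPM ± 10.9 against 26.3 ± 2.48, edgeR adjusted p = 0.000764), Kcnma1 by 0.72 and Kcnj10, a potassium channel of satellite glia, by 0.52, while Kcna1 fell by 0.82 (239 ± 6.47 against 407 ± 24.9, adjusted p = 0.00127). Of 12 calcium channel genes 1 rose, Cacna1c (0.76), also adjusted over the list alone. Of 10 neurotrophic genes 1 fell, Ntrk3 by 0.83 (3 adjusted over the list alone). Of 12 collagens and matrix genes 1 fell, Col3a1 by 0.52 (4 adjusted over the list alone, camera adjusted p = 0.0197, and 0.571 with an estimated correlation). Within clusters 1 and 3 alone, 1 potassium and HCN channel gene rose in each and 0 and 1 fell, 0 and 1 neurotrophic genes fell, 0 and 2 collagen and matrix genes fell, and no calcium channel gene passed edgeR. Adjusted over the list alone, these were 2 and 3 channel genes higher and 2 and 5 lower, 0 and 3 neurotrophic genes lower, 0 and 2 collagen and matrix genes lower, and 0 calcium channel genes.

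In the other lists no gene passed among all genes in glia: noradrenaline synthesis (14 measured), neuropeptides (6), nicotinic and muscarinic receptors (7), adrenergic receptors (5), sodium channels (9), cholesterol synthesis (14), myelin (7), class II antigen presentation (3) and nuclear RNA quality (7). Adjusted over the list alone, 2 neuropeptide genes and 2 myelin genes were lower and 1 adrenergic receptor gene higher in males. The noradrenaline list was lower as a whole (camera adjusted p = 0.0197, and 0.526 with an estimated correlation), with an adjusted p = 0.316 within cluster 1 alone and 0.0224 within cluster 3 alone (0.354 with an estimated correlation). In glia its members Th, Dbh, Slc18a2 and Slc6a2 stood at 16.5%, 16.3%, 9.60% and 9.85% of the neuron level. In fibroblasts they stood at 14.5%, 16.6%, 9.10% and 11.7%. The noradrenaline list may therefore not measure expression by glia. The median of the adrenergic receptors lay at -0.32 and their mean at 0.10. Of the 19 lists, 4 passed fry (injury and regeneration, circadian clock and the sex-linked lists) and 0 passed camera with an estimated correlation.

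Glia clusters 1 and 3 alone gave 95 calls each. Of these, 18 genes were shared, 17 in the same direction, and 11 of the shared genes lay outside the sex-linked lists. The same 4 mice entered both lists. In cluster 3 Kitl, the ligand of the Kit receptor, fell by 2.11 and Ntrk3 fell by 1.45 on the log2 scale, and in cluster 1 Adam12 rose by 1.85 and Cd14 fell by 1.20. DESeq2 gave 23 calls in cluster 1 and 43 in cluster 3, left ganglia alone 24 and 36, and right ganglia alone 9 and 6. Without mouse 7 cluster 3 gave 419 calls, without mouse 8 185, without mouse 2 157 and without mouse 1 47, while cluster 1 gave 64 to 104.

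In neurons, 6 of 14348 genes passed edgeR (759 at an unadjusted p under 0.05, 14 with DESeq2). Uty, Ddx3y, Eif2s3y and Kdm5d, all 4 of the Y-linked list, rose, and of the 6 X-linked genes 2 fell (4 adjusted over the list alone): Xist fell by 5.05 and Tsix fell by 3.96 on the log2 scale. The count was 46 without mouse 1, 67 without mouse 2, 1294 without mouse 7 and 69 without mouse 8. Camera placed immediate early genes (adjusted p = 9.24e-08), collagens (0.00031), noradrenaline synthesis (0.00522) and neuropeptides (0.0189) lower in males, and nuclear RNA quality (0.00522) and calcium channels (0.0429) higher. Each had an adjusted p = 0.583 with an estimated correlation. Across neuron genes the change between the sexes rose with gene span (Spearman correlation 0.315, and -0.0112 with the span trend taken out). Whether these lists follow that trend was not tested. Pooled over mice, sub-cluster 2, with Npy, Gal and the fibroblast marker Dcn among its leading genes, held more of the neurons of females than any other sub-cluster, and sub-cluster 0 more of those of males. In neurons no member of the lists outside the sex-linked ones was called among all genes, and 1 collagen gene fell adjusted over the list alone. Sodium channels, potassium channels, cholinergic receptors, clock genes and the 5 measured steroid hormone receptors passed no list test in neurons.

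**Figure D4:**
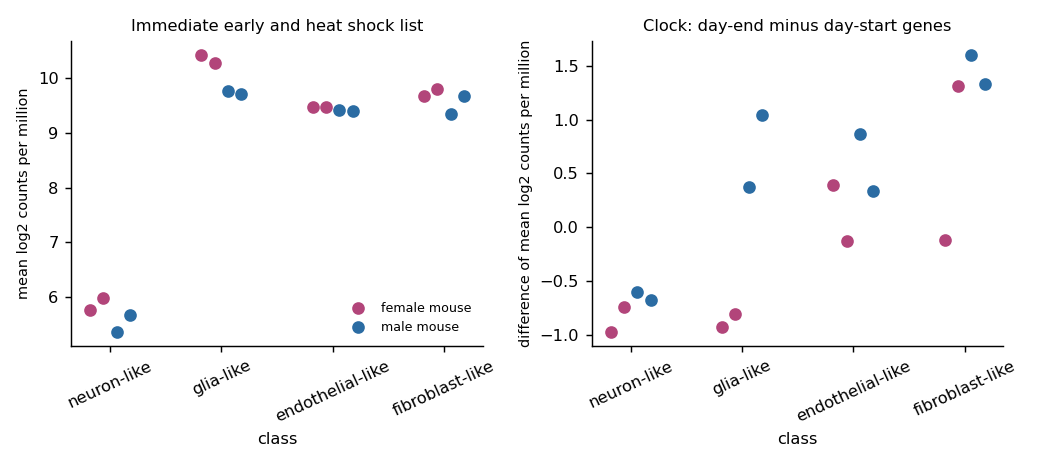
Mean log2 CPM of the immediate early list, and clock genes that peak around the end of the day minus those that peak around its start (log2), in 4 classes and 4 mice. The immediate early mean of both males lay below that of both females in 4 of 4 classes, with a male minus female difference of -0.609 in glia and -0.0628 in endothelial nuclei, and in fibroblasts mouse 8 stood at 9.67 against 9.68 in mouse 1.

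Endothelial nuclei and fibroblasts each held a small set of sex calls besides Xist, Tsix, Ddx3y and Uty. In endothelial nuclei 8 of 8697 genes passed edgeR (475 at an unadjusted p under 0.05, 7 with DESeq2). Col13a1, a transmembrane collagen gene (chromosome 10, 61838236 to 61979108), rose by 1.89 on the log2 scale (150 CPM ± 13.5 in males, 39.6 ± 5.40 in females, adjusted p = 0.00478), and Mgp, an inhibitor of calcification, by 1.40 (491 ± 41.3 against 182 ± 23.2, adjusted p = 0.0136). The calcium channel gene Cacna1e fell by 5.11 (0.536 ± 0.758 against 25.9 ± 2.87, adjusted p = 0.0136). Its mean in males lay below the floor of the endothelial class, 0.984 CPM for 3 counts, so the size of the fall is uncertain. Of 3 measured Y-linked genes 2 rose (3 adjusted over the list alone) and of 6 X-linked genes 2 fell (5 adjusted over the list alone). The calcium channel list was lower (camera adjusted p = 0.000569, and 0.489 with an estimated correlation), with 1 of 4 measured members called, Cacna1e. Leaving out mouse 1 gave 53 calls, mouse 2 21, mouse 7 23 and mouse 8 21.

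In fibroblasts 6 of 5400 genes passed edgeR, and 5 with DESeq2. Angptl7, a secreted angiopoietin-like factor (chromosome 4, 148495183 to 148500460), rose by 2.13 on the log2 scale (915 CPM ± 59.6 against 209 ± 55.6, adjusted p = 0.00138). Gm47283 fell by 1.66 in fibroblasts and by 1.38 in endothelial nuclei, although it is annotated on the Y chromosome, and its counts are uncertain. Of 6 X-linked genes 2 fell (4 adjusted over the list alone). Collagens and matrix genes were higher in males (camera adjusted p = 2.27e-06, and 0.532 with an estimated correlation): 0 of 12 were called among all genes and 7 rose adjusted over the list alone. Immediate early and interferon genes were lower and clock genes higher (each adjusted p = 0.0202, and 0.783 with an estimated correlation). Left ganglia alone gave 0 calls in edgeR (104 at an unadjusted p under 0.05). The count was 28 without mouse 2, 29 without mouse 7 and 59 without mouse 8.

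Class shares did not pass between the sexes. Glia were 68.7% ± 1.81 in males and 73.9% ± 1.71 in females (SD, n = 2), endothelial nuclei 8.14% ± 1.83 and 4.88% ± 0.540, myelinating Schwann nuclei 1.62% ± 0.907 and 0.435% ± 0.0104, and neurons 11.4% ± 3.01 and 9.23% ± 0.766. The exact permutation p was 0.333 for glia, endothelial and myelinating Schwann nuclei, which is the smallest that 2 against 2 mice allow, and 0.667 for neurons.

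The third comparison asked whether the sides differ in another way in males than in females. In endothelial nuclei the coagulation factor gene F5 and the adhesion genes Sele and Selp, which bind leukocytes to activated endothelium, had right-against-left changes that differed between the sexes. There, 9 of 6910 genes passed the edgeR test of the sex by side term (460 at an unadjusted p under 0.05), 8 with a higher and 1 with a lower right-against-left change in males. F5 (chromosome 1, 164151838 to 164220277) differed by 3.75 on the log2 scale (SE 0.51, adjusted p = 0.00026): it was lower on the right in both females and higher on the right in both males. Sele and Selp differed by 1.77 and 1.48, the prostaglandin transporter gene Slco2a1 by 1.79, Angpt2, which acts on the Tie2 receptor, by 2.78, Col15a1 by 2.01, Pawr by 3.01 and the satellite-repeat gene Gm10800 by 6.34. The lymphatic growth factor gene Vegfc differed by -2.57. DESeq2 called 1 gene and the fit without the mouse as a block called 0. The count was 35 without mouse 1, 43 without mouse 2, 4 without mouse 7 and 27 without mouse 8, of which 5, 9, 2 and 6 were among the 9. F5 was the gene that DESeq2 called. With a mouse left out, its sex is left with a single mouse, which is assumed to vary like the other sex. These fits therefore add little to the calls. Without mouse 7 F5 and Vegfc alone of the 9 were called, and Sele and Selp were called without mouse 2 but not without mouse 1, 7 or 8.

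**Figure D5:**
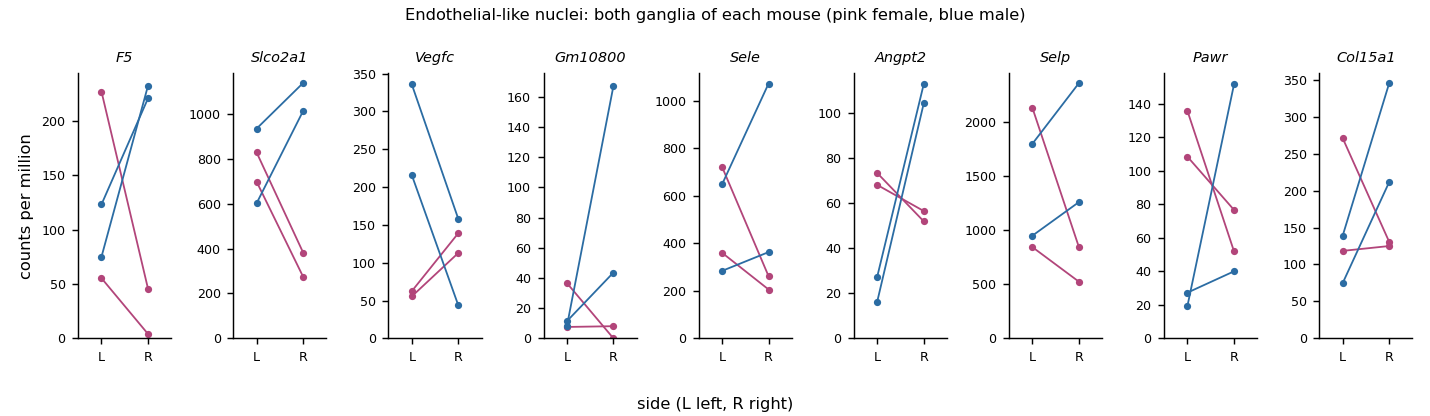
Level (CPM, each gene on its own axis from 0) in left and right endothelial-like nuclei of each mouse for the 9 genes called for the sex by side term; lines join the ganglia of a mouse. F5 was lower on the right in both females and higher on the right in both males.

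In neurons 0 of the genes passed this test (245 at an unadjusted p under 0.05), with Hs3st4, Hoxb5, Car10, Ano3 and Dpp10 at the smallest p (adjusted p from 0.219 to 0.323). Car10 is also among the leading genes of neuron sub-cluster 4. In glia 0 passed (504 at an unadjusted p under 0.05), with Birc3, Chsy3, Rhoj, Trib1 and Ifi47 first (adjusted p = 0.909). DESeq2 called 0 genes in both. Without mouse 1 edgeR called 47 genes in neurons and 76 in glia, without mouse 2 it called 6 in neurons, and without mouse 8 it called 13 and 1.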

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

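The tests of other splits of the ganglia, of the glial cluster mix, of handling and of the clock were chosen only after the results were seen, as were the alternative fits of the sex by side term.

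Of 26 groups of 4 ganglia tested for a value far from the others, 2 held one, and chance gives about 1 in 20. The macrophage share of the right ganglion of mouse 1 was 0.410%, and the other ganglia of the females lay between 1.20% and 1.22%. The endothelial share of the left ganglion of mouse 7 was 12.4%, and the other ganglia of the males lay between 6.42% and 7.16%.

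The right-against-left change differed between the sexes, by a test of the difference itself, for 9 genes in endothelial nuclei: Gm10800 (6.34 on the log2 scale), F5 (3.75), Pawr (3.01), Angpt2 (2.78), Col15a1 (2.01), Slco2a1 (1.79), Sele (1.77), Selp (1.48) and Vegfc (-2.57). These are edgeR calls with the mouse as a block: DESeq2 called F5 alone, and edgeR without the block called 0 genes. Gm10800 also leads the unnamed cluster 7.

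Outside the nuclei used for the comparisons, 17 nuclei without a single hashtag held at least 3 of 6 sensory neuron markers. Of all kept nuclei 40 did, with a median of 67468 UMI counts, and the 23 with a single hashtag all lay in the neuron class. With all kept nuclei clustered, the unnamed cluster held 748 nuclei at a median of 1424.5 UMI counts and was led by the satellite-repeat gene Gm10800. In its summed counts sensory neuron markers stood higher by a mean of 3.06 on the log2 scale, with 5 of 6 at least 2 times higher. Sensory markers were therefore not confined to the few deep nuclei. Superior cervical ganglia are sympathetic, and where these nuclei come from was not tested.

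Splits of the 8 ganglia into 4 against 4, each fitted with the mouse as a block, were compared with the right-against-left count of 0. With a real count of 0, all 32 splits give at least as many calls in each of the 5 classes by construction, which says nothing about chance. The highest count of another split was 1048 in neurons, 174 in glia, 8 in endothelial nuclei, 1 in glia cluster 1 and 83 in glia cluster 3. Among the 8 splits that, like the real one, part all 4 pairs, the highest others were 1048, 87, 0, 1 and 24. Counts this far above 0 in neurons and glia point to a structure of the samples other than side.

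The neuron split with 1048 calls set the left ganglia of mice 1 and 8 and the right ganglia of mice 2 and 7 apart from the rest, and neuron calls between the sexes went from 6 to 1294 without mouse 7. With each library's trend over gene span taken out, 976 genes were called without mouse 7, of which 763 were among the 1294. For the calls between the sexes this argues against that trend as the whole cause and leaves it open as part of it. In the split the same correction gave 239 calls, of which 196 were among the 1048. Called genes higher in the ganglia set apart had a median span of 164378 bp, and the other called genes 7955 bp. The change in the rest against those ganglia fell with span (Spearman correlation -0.475), so the trend stays open as a cause of many calls in the split. A different mix of neuron sub-clusters is a candidate explanation: with sub-clusters balanced, 101 genes were called, against 1282 in equally many nuclei drawn without balance, and with the span trend also taken out 287 against 858. A sex difference in the neurons stays open and was not tested apart from this.

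Of the glia genes called between the sexes, 175 outside the sex-linked lists were called with the glial clusters balanced over mice. Equally many nuclei drawn without balance gave 394. This argues against the mix of these clusters as the whole cause and leaves it open as part of the cause. A different mix within a cluster was not balanced, so it stays open too. Across genes, the change between the sexes was nearly unrelated to gene span in glia (Spearman correlation -0.0444), which argues against that trend as the cause, and taking out so small a trend, which gave 699 calls in place of 544, adds little. The immediate early list was lower in both males than in both females in 4 of 4 classes, although the nearest male and female almost met in fibroblasts (9.67 and 9.68, mean log2 CPM) and endothelial nuclei (9.43 and 9.47), and handling of the tissue that differed between the mice could account for these genes. Its median log2 change of -0.61 in glia was -0.26 within cluster 1 and -0.54 within cluster 3, so the cluster mix stays open as part of the cause for this list. Sex itself predicts the same order in the classes and stays open.

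The clock genes of glia may reflect another phase of the clock at collection in the sexes. Genes that peak around the end of the day stood higher against those that peak around its start in both males than in both females in 2 of the 3 other classes, neurons (0.217) and fibroblasts (0.872), and the sexes overlapped in endothelial nuclei. The fibroblast difference rests on mouse 1, at -0.121, since mouse 2, the other female, stood at 1.31 and the males at 1.60 and 1.33. A phase difference and a sex difference in the clock cannot be told apart, because collection times are not given in the sources used here.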

How the results depend on the processing

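The top Scrublet scores, balanced glial clusters, classes from all nuclei, neuron sub-clusters, crossed pairing and the other fits of the sex by side term were chosen after seeing the data. Of the values that answer a comparison, 258 under alternatives chosen earlier kept their direction and their side of the threshold or moved by less than their spread, 49 moved and 11 reversed. Under the later ones 120 were kept, 38 moved and 2 reversed. The cause of a move or reversal was not tested unless named. Some of the 258 could not have failed: Scrublet marked 0 nuclei, so shares with Scrublet doublets kept equal the main ones. Pooled shares with a ganglion left out hold most of the same nuclei and were judged by the SD over ganglia. The tally is therefore no measure of how robust the results are.

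Nuclei with a single hashtag were 51.2% with a stricter positive quantile, 45.1% with MULTIseqDemux and 32.3% with the margin rule, which left enough nuclei for a test in glia alone. Y-linked transcripts in females then stood at 15.7% of the level in males. The callers also differed by ganglion: MULTIseqDemux left 27 nuclei in the left ganglion of mouse 8. The margin rule gave 2289 of its 3336 nuclei to the right ganglion of mouse 1. The looser and stricter filters kept 99.4% and 81.1% of barcodes. The glia share was 62.9% at resolution 0.3 and 68.0% in all nuclei, and the unnamed share 11.7% at 0.3, 3.86% at 1.0 and 7.24% in all nuclei.

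Between sexes, neurons gave 14 calls with DESeq2, 141 with no filter on low counts, 10 with MULTIseqDemux, 11 with classes from all nuclei and 16 without sub-clusters 3 and 4. Glia gave 331 with DESeq2, 110 with MULTIseqDemux, 29 with the margin rule, 443 in left and 11 in right ganglia alone, and 184 with glial clusters balanced against 403 in equally many nuclei drawn without balance. Endothelial nuclei gave 35 with no filter, and 9 in left and 4 in right ganglia alone. Fibroblasts gave 25 with no filter, 10 with the top Scrublet scores removed and 5 in right ganglia alone. In left ganglia alone, with 12 nuclei in mouse 7, they gave 0 (edgeR, 104 at an unadjusted p under 0.05). Glia clusters 1 and 3 gave 23 and 43 with DESeq2, 139 and 235 with no filter, 24 and 36 in left ganglia alone, 9 and 6 in right ganglia alone and 54 and 118 with the top Scrublet scores removed. Between sides, no filter gave 38 calls in neurons, 7 in glia, 12 in endothelial nuclei, 13 in glia cluster 1 and 12 in glia cluster 3, and in cluster 1 upper quartile scaling gave 1 and the top Scrublet scores removed gave 2. For the sex by side term, no filter gave 43 in neurons, 34 in glia and 34 in endothelial nuclei, where DESeq2 gave 1 and the top Scrublet scores removed gave 28.

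With no replicate block, the sex by side term in endothelial nuclei gave 0 calls in edgeR, and leaving out the block changed no other count of calls between sides in neurons, glia or endothelial nuclei (0 calls, with 144, 276 and 200 genes at an unadjusted p under 0.05). Without the block, glia clusters 1 and 3 gave 2 and 1 calls between sides. Pairing the left ganglion of each female with the right ganglion of the other gave 0 calls between sides in neurons, glia and endothelial nuclei, 3 in glia cluster 1 and 2 in glia cluster 3.

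Leaving out each mouse in turn gave between sexes 46 to 1294 calls in neurons (1294 without mouse 7), 118 (without mouse 1) to 914 (without mouse 7) in glia, 21 to 53 in endothelial nuclei, 9 to 59 in fibroblasts, 64 to 104 in glia cluster 1 and 47 to 419 in glia cluster 3. For the sex by side term it gave 0 to 47 in neurons, 0 to 76 in glia and 4 to 43 in endothelial nuclei. In the fits of the sexes and of the sex by side term the lone mouse is assumed to vary like the other sex. Of the share differences in percentage points, right minus left ran from -1.22 to 1.29 in neurons, -1.17 to 1.41 in glia, -0.223 to 0.0188 in mural, -0.210 to 0.265 in myelinating Schwann and -0.0867 to 0.243 in unnamed nuclei. Male minus female ran from -0.299 to 0.139 in macrophages, -0.915 to 0.220 in perineurial and -0.307 to 0.856 in unnamed nuclei. With the top Scrublet scores removed, macrophages stood at 0.0167 (male minus female) and unnamed nuclei at -0.0567 (right minus left).

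Lists past camera were 0 in neurons, glia, endothelial nuclei and fibroblasts with an estimated correlation. With fry they were 0 for the sides in neurons and endothelial nuclei, and for the sexes 0 in neurons, 4 in glia and 1 in fibroblasts. For the sexes, camera gave 3 in neurons in right ganglia alone, 4 in glia with the margin rule and 5 in endothelial nuclei with classes from all nuclei. In fibroblasts it gave 8 with no filter, 2 in left ganglia alone and 2 with the top Scrublet scores removed. Leaving out each mouse gave for the sides 0 to 9 lists in neurons, 0 to 3 in glia and 1 to 2 in endothelial nuclei, and for the sexes 4 to 11 in neurons, 6 to 11 in glia, 3 to 6 in endothelial nuclei and 3 to 8 in fibroblasts.

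Of single named genes between sexes outside the glia clusters, 1016 values were the same, 272 no longer passed, 9 newly passed and 1 reversed. The reversed value (Per3, male against female, glia) was -0.0181 with the margin rule (edgeR adjusted p = 0.994, from 0.000336 to 0.731 under the other alternatives). Between sexes, recovery of genes changed 2-fold in simulation was lowest in fibroblasts among the 4 classes, at 16%.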

Other observations

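The 595 neuron nuclei fell into 6 sub-clusters. Sub-cluster 2 was led by Gda, Chga, Smoc2, Rgs5, Npy and Gal, sub-cluster 1 by Gfra2 and Kcnn2, and sub-cluster 5 by Syt10 and Bmp3. In sub-cluster 4, with 98 nuclei, 5 of 6 sensory neuron markers were at least 2 times higher than in the other neurons. Its sensory markers stood higher by a mean of 1.90 on the log2 scale, and the endothelial list came next with 1.41. Its leading genes included Edn3, Areg, Slc17a6 and Scn10a and the endothelial gene Flt1. Sub-cluster 3, with 85 nuclei, was led by the glial genes Cdh19, Sox6 and Gpm6b.

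The unnamed cluster 7 held 180 nuclei at a median of 1827.5 UMI counts and was led by satellite-repeat and mitochondrial genes. Slc6a2 stood there at 2860 CPM and Dbh at 1497 CPM, against 3076 and 1203 CPM in neurons.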
